A study of Mus musculus with 9 samples.

How the data were processed

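RNA of lung cells was measured by sequencing in 9 libraries from female C57BL/6J mice, in 3 groups of 3 libraries. The groups, taken from the sample labels, were wild-type mice challenged with phosphate-buffered saline (WT PBS, replicates 1, 2 and 3), wild-type mice challenged with ovalbumin (WT OVA, replicates 5, 6 and 9) and DJ-1 knockout mice challenged with ovalbumin (DJ-1 KO OVA, libraries DJ1_KO_OVA_263, DJ1_KO_OVA_266 and DJ1_KO_OVA_267). The time label was 7 weeks for all 9 libraries. The labels give no batch, no knockout group challenged with saline and no numbers that pair libraries across groups.

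Per the submitters' processing notes, the authors used Trimmomatic, HISAT2 and HTSeq with the genome build GRCm38.p6; the versions and the role of each tool are not given in the sources used here. Libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. The deposited table holds FPKM, read counts divided by gene length and library size, for 55851 genes in the 9 libraries, with gene symbols, positions and lengths, per the file headers.

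The FPKM values were examined for the depth behind them. In each library, FPKM multiplied by gene length was a whole multiple of a single step for 100% of the values above 0, within a tolerance of 0.01 reads, so the reads per gene were recovered. The 9 libraries held 20812192 to 29080130 recovered reads. The library sizes that the authors divided by were not these totals: they followed median-of-ratios size factors of the recovered reads, with the 2 sets of relative sizes equal to 5 digits. The ratio of the size used to the recovered total ran from 0.8903 in WT OVA replicate 9 to 1.215 in DJ1_KO_OVA_263. The deposited FPKM are therefore already scaled between libraries on the median gene.

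Values were analysed as log2(FPKM + 0.5) for the 17716 genes with a mean FPKM of at least 0.2 over the 9 libraries. A single limma fit (limma 3.58.1, R 4.3.3) with a mean for each group and 6 residual degrees of freedom was used for the 3 comparisons, with an empirical Bayes variance that followed the mean level (limma-trend). Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are differences of group means on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Means are given in FPKM with the SD over 3 libraries, so their ratio can differ from the fold. The p-values measure the spread between libraries; the labels do not say whether each library is a single animal, so that spread may be technical. The count model planned for deposited counts was not used, because the deposited unit is FPKM; a limma-voom fit on the recovered reads was added as an alternative.

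Named genes were chosen by a rule fixed before the data were examined. For each of the first 2 comparisons it takes the 10 largest rises and 10 largest falls among called genes whose replicate values do not overlap between the groups and whose mean FPKM is at least 1 in the higher group, without predicted genes and variable segments; for the third comparison it takes 5 and 5. It also takes up to 4 members with the smallest p of each gene list described, and a set of key genes. Genes named outside the rule are said to have been chosen after their values were seen. The 43 gene lists, 23 of cell type markers and 20 of pathways or checks, were also fixed before the data were examined; 41 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. For each list, calls were counted over all tested genes and adjusted over the list alone. Lists of nuclear-retained RNA, mitochondrially encoded proteins and ribosomal proteins were added after the data had been seen. Where a symbol belonged to several gene identifiers, it was given to the identifier with the highest mean, and 119 identifiers went by their own name.

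The test was checked on simulated reads for the same 17716 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. For WT OVA against WT PBS it recovered 23% of the 2-fold and 86% of the 4-fold changes, with 5 false calls. For DJ-1 KO OVA against WT OVA the recovered shares were 10% and 87%, with 2 false calls, and for DJ-1 KO OVA against WT PBS they were 20% and 83%, with 3. The simulated genes were drawn independently, with the same spread in every library. Only genes with a mean FPKM of at least 1 in the reference group were changed. The false calls and recovered shares therefore do not cover correlated genes, outlying libraries or changes in low genes. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1, so comparisons rest on the model fitted across genes.

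Alternatives changed the pseudocount to 0.1 or 1, the filter, the scaling between libraries, the variance model, the libraries in the fit and the threshold, and left out each library in turn. After the data had been seen, 3 were added: limma-voom, removal of a smooth trend on gene length and GC content from each library, and library weights estimated gene by gene. The last was added because the planned estimate of library weights, by limma's default method, stopped with convergence warnings; the results of both are given. GC content came from the longest transcript of each gene in a GENCODE annotation of GRCm38 and was available for 97.8% of the tested genes. For the comparison of the OVA response with the knockout difference, which share the WT OVA libraries, 100 sets of unchanged groups were simulated from independent normal values with each gene's residual SD; this leaves out any correlation between genes. It took the place of a permutation of residuals, which could not represent unchanged groups with 3 libraries each; the change was made after the first output had been seen.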

Results

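RNA of lung cells from wild-type and DJ-1 knockout mice was sequenced in 9 libraries to ask how ovalbumin challenge, a model of allergic airway inflammation, alters gene expression and how loss of DJ-1 alters the challenged lung. DJ-1, encoded by Park7, is a protein that protects cells against oxidative stress. The 3 libraries of each group were compared with the other groups, and 12636 to 12983 genes per library had an FPKM of at least 1. Recovered depth was 21140506, 21465051 and 29080130 reads in WT PBS replicates 1, 2 and 3, and 20812192, 23413505 and 22090710 reads in WT OVA replicates 5, 6 and 9. The knockout libraries DJ1_KO_OVA_263, DJ1_KO_OVA_266 and DJ1_KO_OVA_267 held 28339649, 24023475 and 23838275 reads.

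Park7 (ENSMUSG00000028964, chromosome 4, 150897133 to 150914437, GRCm38) was measured first as a check of the genotype labels. Its FPKM was 46.7 ± 8.91 (SD, n = 3) in WT PBS, 57.2 ± 3.78 in WT OVA and 5.08 ± 1.92 in DJ-1 KO OVA. The difference between the OVA groups was -3.42 on the log2 scale (SE 0.25, adjusted p = 0.00019, limma). Between 241 and 427 reads of Park7 remained in each knockout library, so its transcript was reduced but still detected. The 4 Y-linked genes examined had 0 reads in the 9 libraries.

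The first comparison, WT OVA against WT PBS, addresses the response of the wild-type lung to challenge. Genes of airway mucus production and of the epithelial response to interleukin-13 were higher in the WT OVA libraries as a group: all 19 measured members had a positive difference, with a median of 1.15 on the log2 scale. Clca1, a secreted goblet cell protein, was at 543, 56.4 and 487 FPKM in WT OVA replicates 5, 6 and 9 and averaged 6.06 ± 6 FPKM (SD, n = 3) after PBS. Retnla, a secreted protein of type 2 inflammation, averaged 3740 ± 2880 and 121 ± 58.2 FPKM, and Chil4, a chitinase-like protein, 64.7 ± 53.4 and 0.391 ± 0.434 FPKM. The gel-forming mucin Muc5ac was at 2.96 ± 2.1 and 0.209 ± 0.0517 FPKM, a 4.01-fold difference. None of these 4 passed over all genes, with adjusted p = 0.29 for Clca1, 0.39 for Retnla, 0.39 for Chil4 and 0.72 for Muc5ac (limma). Over all genes 0 of the 19 list members passed, and 15 passed when adjusted over the list alone. The list was past the threshold in camera (adjusted p = 9.9e-24), and its adjusted p was 0.39 with an estimated correlation.

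Among cytokine genes in the same comparison, Il13 was at 1.84 ± 1.03 FPKM (SD, n = 3) after OVA and 0.371 ± 0.115 after PBS, Il5 at 2.61 ± 0.502 and 1.23 ± 0.88, and Il4 at 1.03 ± 0.554 and 0.416 ± 0.13. The macrophage chemokines Ccl8 and Ccl17 differed 17.2-fold and 14.7-fold, and the eosinophil attractant Ccl11 differed 1.87-fold. The alternative macrophage activation list (median log2 difference 0.78, camera adjusted p = 2.7e-06) and the chemokine list (median 0.7, adjusted p = 4.5e-06), each with adjusted p = 0.75 with an estimated correlation, had 4 of 17 and 4 of 29 members past the threshold when adjusted over the list alone, and 0 of either over all genes. All 19 measured genes of ciliated cells were also higher, by a median of 0.81, with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 4.5e-06; adjusted p = 0.75 with an estimated correlation). After rescaling to equal FPKM sums the medians were 0.48 for the macrophage list, 0.39 for chemokines and 0.53 for ciliated cells. WT OVA replicate 6 had the highest ciliated list mean of the 9 libraries, 2.87, and without it the adjusted p was 0.09. Lists lower in WT OVA in camera were Notch (adjusted p = 0.003), neutrophil (0.0066), B cell (0.0072) and smooth muscle and pericyte genes (0.0075). The neutrophil and B cell medians were -0.25 and -0.28. Over all genes 0 of their members passed, and 0 lists passed with an estimated correlation. The camera adjusted p was 0.077 for neutrophils without WT PBS replicate 2 and 0.098 for B cells without WT OVA replicate 6. Eosinophil genes were not called: Prg2, a granule protein, was at 2.5 ± 2.15 and 0.289 ± 0.105 FPKM (adjusted p = 0.73), and Epx had at most 3 reads in any library.

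Across the 17716 tested genes a single gene passed in WT OVA against WT PBS. Tmem150a, a membrane protein gene on chromosome 6 (72355447 to 72359762), rose from 0.219 ± 0.193 to 2.56 ± 0.553 FPKM (SD, n = 3), which is 4.31-fold (adjusted p = 0.043, limma), and fell below the threshold in 11 of 19 alternative settings. At an unadjusted p under 0.05 there were 1146 genes, 6.47% of those tested, and limma-voom called 0. The groups did not overlap for 14.8% of genes, where chance gives 10%. WT OVA replicate 6 had lower values of these mucus genes than the other 2 OVA replicates: its Muc5ac was 0.556 FPKM, against 4.46 and 3.85. Without that library 14 genes passed, all higher after OVA, 8 of them in the mucus list, and 0 passed without WT PBS replicate 1 or 2 or WT OVA replicate 5 or 9. Ribosomal protein genes were higher in WT OVA for 34 of 34 members (median 0.54) and mitochondrially encoded protein genes for 13 of 13 (median 0.64), with 0 past the threshold. These medians were 0.23 and 0.32 after rescaling to equal FPKM sums, 0.22 and 0.3 with quantile normalization, and 0.43 and 0.24 with the length and GC trend removed.

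**Figure D1:**
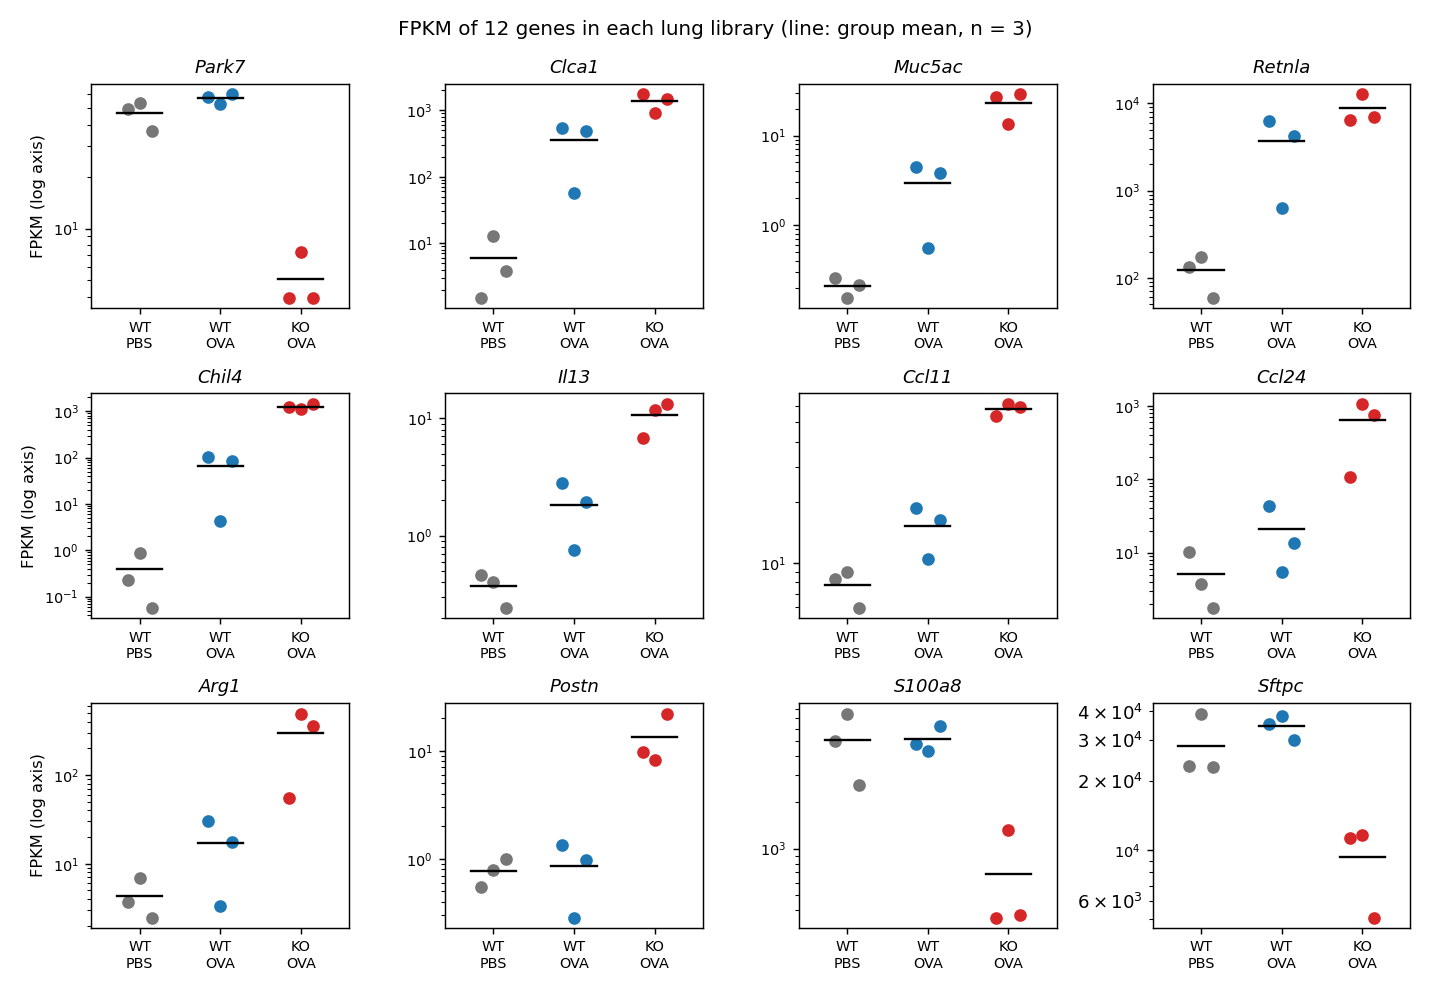
FPKM on a log axis for 12 genes in each of the 9 libraries, by group, with a line at the group mean. Park7 lay at 3.96 to 7.29 FPKM in the knockout libraries, and WT OVA replicate 6, the middle point of its group, had the lowest Clca1, Muc5ac, Retnla and Chil4 of the WT OVA libraries.

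The second comparison, DJ-1 KO OVA against WT OVA, addresses the effect of DJ-1 loss in the challenged lung. In the type 2 cytokine list the members that passed were higher in the knockout libraries. Il13 rose from 1.84 ± 1.03 to 10.6 ± 3.42 FPKM (SD, n = 3), 4.95-fold (adjusted p = 0.0072, limma), and the epithelial alarmin Il33 rose from 33.7 ± 0.613 to 86.3 ± 27.6 FPKM. Gata3, the transcription factor of type 2 lymphocytes, rose 3.67-fold, and Il17rb, a subunit of the interleukin-25 receptor, 2.81-fold. In this list 6 of 14 measured members rose and 0 fell (camera adjusted p = 0.0015; adjusted p = 0.57 with an estimated correlation). The number was 10 after rescaling to equal FPKM sums and ran from 3 to 6 with single libraries left out, lowest without WT OVA replicate 6. Without WT OVA replicate 6 or 9 the adjusted p of Il33 was 0.052 and 0.053. Il4 (2.03 ± 0.945 against 1.03 ± 0.554 FPKM) and Il5 (3.55 ± 0.803 against 2.61 ± 0.502) did not pass.

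Mucus and macrophage genes included the largest rises. Slc26a4, the epithelial anion exchanger pendrin, rose 13.1-fold to 58.9 ± 4.84 FPKM, Retnlb 7.33-fold, Muc5ac 7.95-fold to 23.2 ± 8.46 FPKM and Pigr, the transporter of secretory antibody, 2.59-fold. In the mucus list 10 of 19 members rose and 0 fell (camera adjusted p = 6.1e-08; adjusted p = 0.57 with an estimated correlation). Chil4 rose 36-fold, from 64.7 ± 53.4 to 1270 ± 176 FPKM (SD, n = 3, adjusted p = 0.013), the eosinophil chemokine Ccl24 28.8-fold, from 20.8 ± 19.9 to 646 ± 492, and Arg1, arginase of alternatively activated macrophages, 16.6-fold, from 17.2 ± 13.6 to 302 ± 225. In the alternative macrophage activation list 5 of 17 members rose and 0 fell (camera adjusted p = 0.00059; adjusted p = 0.65 with an estimated correlation). After rescaling to equal FPKM sums 17 mucus and 12 macrophage members were higher, and without DJ1_KO_OVA_267 only 3 and 1. The knockout libraries were not alike in this list: its mean was 6.02 in DJ1_KO_OVA_263, below the 6.26 of WT OVA replicate 5, and 7.7 and 7.56 in DJ1_KO_OVA_266 and DJ1_KO_OVA_267. Arg1 was at 55.3, 496 and 355 FPKM in these 3 libraries and Ccl24 at 108, 1070 and 759 FPKM. Clca1 (5.38-fold, adjusted p = 0.076), Retnla (3.25-fold, adjusted p = 0.14) and Chil3 (3.04-fold, adjusted p = 0.14) did not pass. The other largest rises were Fbp1, a gluconeogenic enzyme (18-fold), the immunoglobulin heavy chain Ighg1 (14.1-fold), Ocstamp, a fusion protein of osteoclasts and macrophages (11.9-fold), the macrophage elastase Mmp12 (10.1-fold), the matricellular protein Postn (9.85-fold) and the activin subunit Inhba (9.24-fold). Low values in WT OVA replicate 6 raised some of these folds above the ratio of the FPKM means. Chil4 was at 4.24 FPKM in that library, against 105 and 84.8 in WT OVA replicates 5 and 9. Fbp1 was at 0.462, against 41.1 and 26.7. Without DJ1_KO_OVA_267 the adjusted p was 0.057 for Chil4, 0.052 for Muc5ac, 0.05 for Ocstamp, 0.066 for Ccl24 and 0.087 for Arg1. Without WT OVA replicate 6 or 9 it was 0.053 and 0.052 for Ccl24 and 0.063 and 0.056 for Arg1. Fbp1 ran from 0.055 to 0.17 and Mmp12 from 0.05 to 0.15 without DJ1_KO_OVA_266, DJ1_KO_OVA_267 or WT OVA replicate 5, 6 or 9.

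In the lists of matrix, cell cycle and T cell genes the members that passed were higher in DJ-1 KO OVA. In the fibroblast and matrix list 13 of 19 members rose and 0 fell (camera adjusted p = 3.3e-08; adjusted p = 0.57 with an estimated correlation), among them Postn, Col3a1 (40.1 ± 1.44 to 190 ± 98.2 FPKM, SD, n = 3) and Fn1 (44.4 ± 15.8 to 247 ± 120). In the cell cycle list 18 of 23 rose and 0 fell (camera adjusted p = 1.3e-10; adjusted p = 0.58 with an estimated correlation), including the replication helicase subunit Mcm3 (3.1-fold) and the mitotic kinases Aurkb (3.37-fold) and Plk1 (3.46-fold). In the T cell list 8 of 20 rose and 0 fell (camera adjusted p = 5.3e-06; adjusted p = 0.62 with an estimated correlation), with Il2ra at 2.33-fold and Cd4 at 3.57-fold. Genes of the unfolded protein response rose in 8 of 18 cases and fell in 2 (camera adjusted p = 0.02; adjusted p = 0.61 with an estimated correlation), with the chaperone Hspa5 at 142 ± 10.1 and 409 ± 143 FPKM and the cochaperone Dnajc3 at 20.8 ± 0.608 and 50.5 ± 10.6. After rescaling to equal FPKM sums, 17 matrix, 23 cell cycle, 13 T cell and 11 unfolded protein response genes were higher and 0 lower. With single libraries left out these numbers ran from 4 to 13, 2 to 20, 0 to 11 and 1 to 9, and each was at its lowest without DJ1_KO_OVA_267; without WT OVA replicate 6 they were 7, 2, 0 and 2, and without replicate 9 they were 5, 2, 1 and 3. Without DJ1_KO_OVA_266 the camera adjusted p of the unfolded protein response was 0.1. Without DJ1_KO_OVA_267 the adjusted p was 0.052 for Aurkb, 0.06 for Plk1, 0.066 for Il2ra, 0.087 for Cd4 and 0.051 for Hspa5. Without WT OVA replicate 6 it was 0.058 for Plk1, 0.056 for Il2ra, 0.083 for Cd4 and 0.053 for Hspa5, without replicate 9 it was 0.057 for Plk1, 0.081 for Cd4 and 0.051 for Hspa5, and without replicate 5 it was 0.058 for Cd4. DJ1_KO_OVA_263 had the highest means of the T cell list (5.15) and the cell cycle list (4).

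In the lists of neutrophil, B cell and lung epithelial genes the members that passed were lower. In the neutrophil list 8 of 13 members fell and 0 rose (camera adjusted p = 2.2e-05; adjusted p = 0.57 with an estimated correlation): the surface marker Ly6g fell from 11.5 ± 2.85 to 1.8 ± 0.632 FPKM (SD, n = 3) and the calcium-binding S100a8 from 5100 ± 1040 to 685 ± 554. In the B cell list 6 of 13 fell and 0 rose (camera adjusted p = 0.0011; adjusted p = 0.62 with an estimated correlation), with Ms4a1 at 19.3 ± 4.57 and 7.16 ± 4.2 FPKM. Of alveolar type 2 genes 3 of 13 fell, including Lamp3 (229 ± 47.7 to 107 ± 38.9 FPKM), while the surfactant gene Sftpc, at 34600 ± 4150 and 9340 ± 3680 FPKM, did not pass (adjusted p = 0.055). Of club cell genes 3 of 13 fell, including Scgb3a2 (2600 ± 1180 to 452 ± 70.3 FPKM), and Scgb1a1 did not pass (adjusted p = 0.3). Alveolar type 1, ciliated, endothelial and cardiomyocyte lists had 3 of 12, 4 of 19, 1 of 15 and 2 of 5 members lower, with camera adjusted p = 0.026, 0.0065, 0.0026 and 0.046. With an estimated correlation, the adjusted p was 0.65 for alveolar type 2 cells, 0.75 for club, alveolar type 1 and endothelial cells, 0.8 for ciliated cells and 0.57 for cardiomyocytes. The endothelial list mean was 0.97 in DJ1_KO_OVA_263, 3.24 in DJ1_KO_OVA_266 and 1.93 in DJ1_KO_OVA_267, and without DJ1_KO_OVA_263 the camera adjusted p was 0.076 for endothelial cells and 0.072 for cardiomyocytes. Without WT OVA replicate 6 it was 0.27 for ciliated cells, 0.055 for club cells, 0.067 for alveolar type 1 cells and 0.076 for cardiomyocytes, and for alveolar type 1 cells it was 0.064 without WT OVA replicate 9 and 0.088 without DJ1_KO_OVA_267. With quantile normalization it was 0.23 for alveolar type 2, 0.063 for alveolar type 1 and 0.11 for club cells. With the length and GC trend removed it was 0.12 for cardiomyocytes, whose list median went from -1.02 to -0.5. Rescaling to equal FPKM sums raised the median of all genes by 0.524 on the log2 scale. After rescaling to equal FPKM sums, 2 B cell genes were lower and 1 higher, with a list median of -0.12 in place of -0.71, and 5 neutrophil, 2 alveolar type 2, 1 alveolar type 1, 3 ciliated, 1 endothelial and 1 cardiomyocyte genes were lower and 0 of these higher; of club cell genes 3 were lower and 1 higher. With single libraries left out the number of lower members ran from 2 to 9 for neutrophils and 0 to 9 for B cells, both lowest without DJ1_KO_OVA_267, and reached 0 for each of the other 6 lists; it was 12 for endothelial cells without DJ1_KO_OVA_266. Among the genes, the adjusted p without DJ1_KO_OVA_267 was 0.066 for S100a8, 0.065 for Scgb3a2, 0.097 for Ms4a1 and 0.17 for Lamp3, and S100a8 had 0.051 without WT OVA replicate 9. Lamp3 ran from 0.092 to 0.13 without WT OVA replicate 5, 6 or 9, and Ms4a1 from 0.06 to 0.085 without these or DJ1_KO_OVA_263.

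Eosinophil, airway progenitor and antioxidant genes, which the study's title or the function of DJ-1 point to, were not called as lists. Of 9 eosinophil genes 1 fell, Ear1, a ribonuclease also made by alveolar macrophages (223 ± 43.4 to 14.2 ± 4.24 FPKM, SD, n = 3), and 0 rose (camera adjusted p = 0.58). Prg2 was at 10.2 ± 8.27 against 2.5 ± 2.15 FPKM, Siglecf at 9.65 ± 5.86 against 13.3 ± 2.16 and Ccr3 at 1.37 ± 0.977 against 0.784 ± 0.509, and none of the 3 passed. The knockout libraries differed: the eosinophil list mean was 1.87 in DJ1_KO_OVA_263, 3.32 in DJ1_KO_OVA_266 and 3.48 in DJ1_KO_OVA_267. Prg2 was at 0.693, 15.1 and 15 FPKM in these libraries. The lowest camera adjusted p of this list over the alternative settings was 0.14. Of 12 measured basal and airway progenitor genes 1 rose, the laminin receptor subunit Itga6 (1.77-fold, adjusted p = 0.047; list adjusted p = 0.33 in camera); Krt5 was at 2.85 ± 1.52 against 1.57 ± 1.4 FPKM, and Trp63 was below the filter. In the antioxidant list 2 of 23 members rose and 5 fell (camera adjusted p = 0.2), with Gclc, a glutathione synthesis enzyme, 2.37-fold higher and Sod1 at 42.1 ± 14.4 against 124 ± 16 FPKM; the list median was -0.36. After rescaling to equal FPKM sums the antioxidant list had 7 members higher, 1 lower and a median of 0.26. That rescaling raised the median of all genes by 0.524, so the list still lay below the median gene. With the same rescaling 4 airway progenitor genes were higher and 0 lower, with a list median of 0.87 in place of 0.3. For eosinophil genes 1 was then higher and 1 lower, and the list median went from -0.09 to 0.19. The quinone reductase Nqo1 fell from 3.3 ± 0.893 to 1.44 ± 0.381 FPKM, and Nfe2l2 and Hmox1 did not pass. With any of the WT OVA replicates 5, 6 and 9, DJ1_KO_OVA_263 or DJ1_KO_OVA_267 left out, the adjusted p was 0.087 to 0.15 for Itga6, 0.051 to 0.088 for Gclc and 0.053 to 0.13 for Nqo1. Sod1 had 0.065 without DJ1_KO_OVA_267 and 0.053 and 0.051 without WT OVA replicates 6 and 9.

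**Figure D2:**
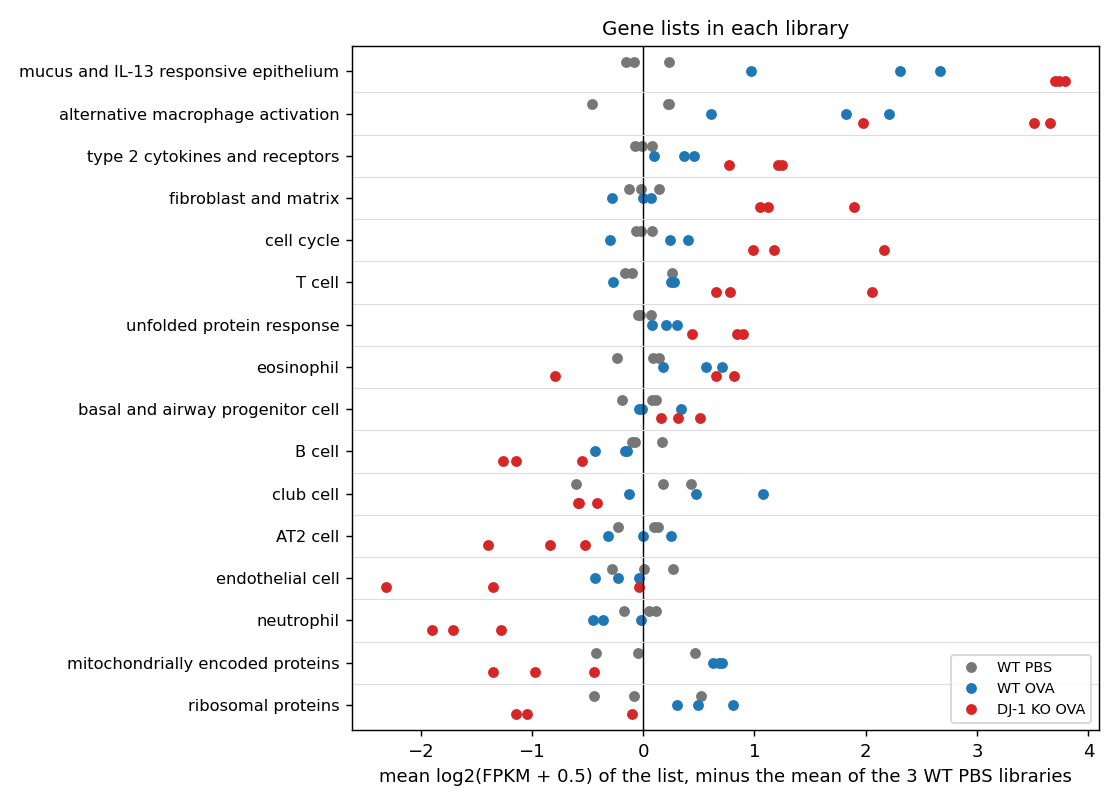
Mean log2(FPKM + 0.5) of 16 gene lists in each library, minus the mean of the 3 WT PBS libraries. The mucus list lay above all WT libraries in the 3 knockout libraries, while DJ1_KO_OVA_263 lay apart from the other 2 for the T cell, cell cycle and eosinophil lists.

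The largest falls included Park7 itself and mitochondrial genes. Besides Park7 (10.7-fold lower), they were the mitochondrial genes mt-Tg (9391 to 9458), mt-Nd3 (9459 to 9806) and mt-Tr (9808 to 9875), which lie next to each other in the mitochondrial genome, with mt-Nd3 at 89.3 ± 3.41 and 6.01 ± 3.79 FPKM (SD, n = 3). The genes beside this block, mt-Co3 (8607 to 9390) and mt-Nd4l (9877 to 10173), differed by less, at -1.97 and -1.12 on the log2 scale. In the WT OVA libraries mt-Co3 was at 103 to 125 FPKM and mt-Co1, another mitochondrial gene, at 13200 to 15100. The genes mt-Co1, mt-Co3 and mt-Nd4l were chosen after their values were seen. Whether the assignment of reads plays a part in the fall of mt-Tg, mt-Nd3 and mt-Tr was not tested. Hmgn2, a nucleosome-binding protein gene on chromosome 4 (133964738 to 133968650), fell from 45.3 ± 8.48 to 2.37 ± 0.572 FPKM. Fabp1 (17.5-fold lower), Ear1 (15.4-fold), Stfa2l1 (12.3-fold), Stfa1 (12-fold) and Cstdc4 (11.6-fold) completed the 10; Stfa1, Stfa2l1 and Cstdc4 are related cystatin genes on chromosome 16, and Ear1 belongs to a family of close copies, so their reads can be divided uncertainly between copies.

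In total 2510 genes passed in DJ-1 KO OVA against WT OVA, 1051 higher and 1459 lower, and 1606 of them differed at least 2-fold. The direction split depended on scaling: 41.9% of calls were higher with the deposited scaling, and 87.9% of 5176 after rescaling to equal FPKM sums, which shifts the median of all genes by 0.524 on the log2 scale. The count was 286 without DJ1_KO_OVA_267, 5694 without DJ1_KO_OVA_266, 1197 without DJ1_KO_OVA_263, and 548, 448 and 477 without WT OVA replicates 5, 6 and 9. Ribosomal protein genes were lower for 34 of 34 members (median -1.31, 19 past the threshold) and mitochondrially encoded protein genes for 13 of 13 (median -1.45, 9 past). With quantile normalization these medians were -0.53 and -0.55. The log2 difference followed gene length across genes, with a Spearman rho of 0.43, and genes are not independent replicates. After a trend on length and GC content was removed, 2264 genes passed, of which 1594 were among the 2510; the medians were then -1.04 for ribosomal protein genes, with 17 past, and -0.65 for mitochondrially encoded ones, with 3 past. The mitochondrial share of reads was 1.97% to 2.67% in the knockout libraries and 4.27% to 4.62% in the WT OVA libraries. The 3 knockout libraries correlated with each other at 0.928 to 0.961, and the 3 WT OVA libraries at 0.973 to 0.978. Between these groups the correlations were 0.891 to 0.964, so the closest pair across groups was closer than any pair of knockout libraries. The labels name no batch, so genotype and any batch shared by the knockout libraries cannot be told apart.

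**Figure D3:**
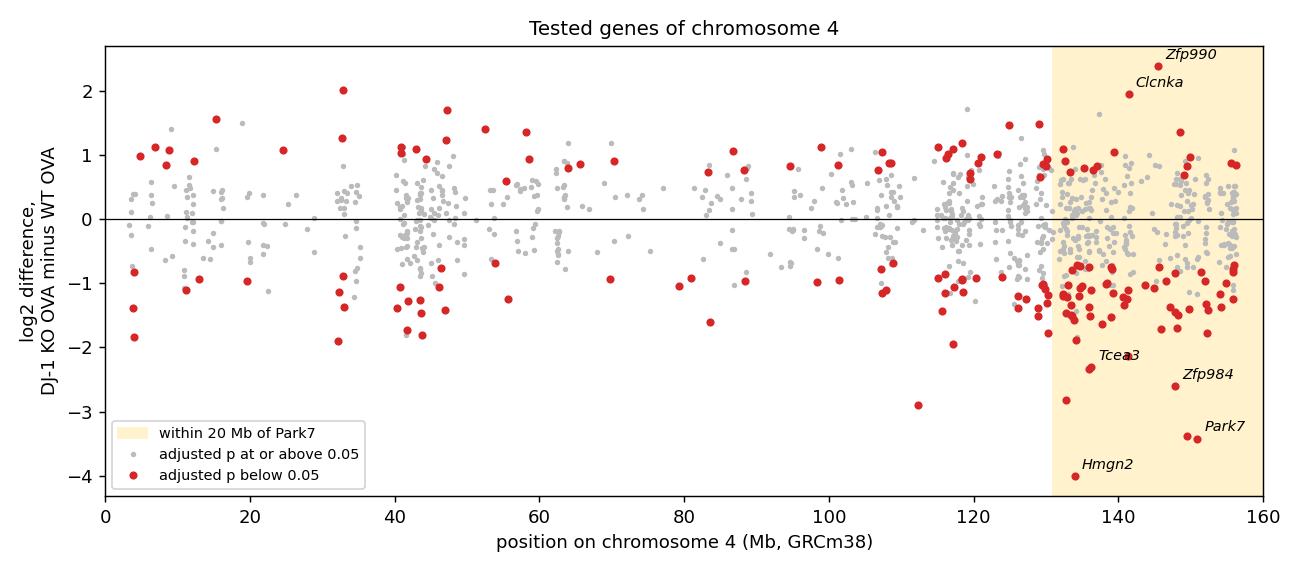
Log2 difference between DJ-1 KO OVA and WT OVA for each tested gene of chromosome 4 by position in Mb (GRCm38), with called genes in red and the 20 Mb around Park7 shaded. In the shaded region 77 of 366 genes other than Park7 were called, 62 of them lower in the knockout, and from 150 to 160 Mb, where Park7 lies, 14 of 99 were called.

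The third comparison, DJ-1 KO OVA against WT PBS, combines challenge and genotype, since no knockout group challenged with PBS was analysed here. All 19 measured mucus genes rose (camera adjusted p = 8.4e-23; adjusted p = 0.21 with an estimated correlation): Clca1 averaged 1380 ± 442 FPKM (SD, n = 3) against 6.06 ± 6, and Chil4 averaged 1270 ± 176 against 0.391 ± 0.434. Rnase2a, a ribonuclease of a family with close copies, averaged 1000 ± 705 against 0.14 ± 0.072, Fbp1 251 ± 186 against 0.193 ± 0.18, and Ccl24 646 ± 492 against 5.21 ± 4.36. Il4, Il5 and Il13 rose 2.63-fold, 2.51-fold and 12.4-fold (adjusted p = 0.031, 0.033 and 0.00058, limma). Il4 ran from 0.06 to 0.13 without WT PBS replicate 1, 2 or 3 or DJ1_KO_OVA_267, and Il5 from 0.08 to 0.12 without WT PBS replicate 1 or 3 or DJ1_KO_OVA_267. Besides the genes mt-Tg, Hmgn2 and Fabp1, the largest falls were Lst1 (332 ± 55.1 to 35.8 ± 33.9 FPKM) and Ifitm6 (170 ± 29.1 to 17.3 ± 14.9). Of neutrophil genes 9 of 13 fell and of cell cycle genes 17 of 23 rose. With an estimated correlation, the adjusted p was 0.21 for neutrophils and 0.35 for cell cycle. The number of cell cycle genes that rose was 2, 4 and 9 without WT PBS replicates 1, 2 and 3, and 13, 20 and 8 without DJ1_KO_OVA_263, DJ1_KO_OVA_266 and DJ1_KO_OVA_267.

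In DJ-1 KO OVA against WT PBS 1513 genes passed, 721 higher and 792 lower. After rescaling to equal FPKM sums, 68.4% of 1407 calls were higher, against 47.7% with the deposited scaling. The count was 436, 532 and 993 without WT PBS replicates 1, 2 and 3, 3897 without DJ1_KO_OVA_266 and 486 without DJ1_KO_OVA_267. Of the genes higher in this comparison 534 were also higher in DJ-1 KO OVA against WT OVA, where independent lists would share 42.8, and of those lower 556 were shared, where independent lists would share 65.2; 0 were called in opposite directions. Both comparisons use the same knockout libraries; part of the excess may come from these shared libraries. Simulated unchanged groups shared a median of 0 calls, but such groups give almost no calls to share, so this does not measure that part.

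The OVA response and the knockout difference share the WT OVA libraries with opposite signs. Across genes their log2 differences had a correlation of -0.35, and simulated unchanged groups gave -0.5. The covariance was -0.088 against a simulated -0.052, a difference of -0.036. Tmem150a was the only gene called in both, higher after OVA and lower in the knockout, where independent lists would share 0.082. Without WT OVA replicate 6, 5 genes were called in both in the same direction and 3 in opposite directions, and without replicate 5 or 9 there were 0. The 2 estimates of library weights gave 255 and 179 genes in the same direction and 1085 and 730 in opposite directions.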

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

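Limma-voom on recovered reads, removal of the length and GC trend and gene-by-gene library weights were chosen after the data had been seen. For WT OVA against WT PBS, where 1 gene passed, 0 passed with a pseudocount of 0.1, a minimum mean FPKM of 1, rescaling to equal FPKM sums, quantile normalization, a fit of only the 2 groups, limma-voom (1112 genes at an unadjusted p under 0.05) or the trend removed, and 2 without a filter. For DJ-1 KO OVA against WT OVA the count of 2510 became 1606 at 2-fold or more, 645 without a filter, 5176 after rescaling to equal FPKM sums and 1131 in a fit of only the 2 groups; limma-voom called 3193, sharing 2393. For DJ-1 KO OVA against WT PBS the 1513 became 669 without a filter and 700 in a fit of only the 2 groups. Leaving out single libraries gave 0 to 14, 286 to 5694 and 436 to 3897 genes in the 3 comparisons. Planned library weights, whose default estimate stopped with convergence warnings, gave 2230, 9560 and 11869 genes; the gene-by-gene estimate gave 1582, 8827 and 9712. Both gave most weight to WT PBS replicate 1 (15.9 and 8.46) and DJ1_KO_OVA_267 (4.91 and 3.14), so these counts rest largely on single libraries. For the other changes of count the cause was not tested.

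Of 41 gene lists, 14, 15 and 17 passed in camera in the 3 comparisons; with an estimated correlation 0, 0 and 0 passed (smallest adjusted p 0.39, 0.57 and 0.21), and with fry 0, 10 and 10. Leaving out single libraries gave 9 to 19, 13 to 17 and 16 to 22 lists. The correlation of the OVA response with the knockout difference was -0.315 after rescaling to equal FPKM sums, -0.314 with quantile normalization, -0.252 and -0.267 with the 2 library weights, -0.302 with limma-voom and -0.238 with the trend removed, and lay between -0.401 and -0.358 without single WT OVA libraries. Of 540 values of genes that the naming rule takes, 220 passed the threshold; 89 of these passed in every setting run, 131 fell below it in at least 1 setting, and 0 reversed while called. In DJ-1 KO OVA against WT OVA, Fbp1, Nqo1 and Lamp3 fell below the threshold in 9 of 20 settings each, Mmp12 in 8, Arg1 in 5 and Chil4 and Muc5ac in 1. Rescaling by median-of-ratios moved little, since the deposited values already follow it, and says nothing about scaling. Planned count models for deposited counts were not run, because the unit is FPKM. No paired analysis was possible because the groups share no replicate numbers. At this spread the test recovered 10% to 23% of simulated 2-fold changes, so genes not called are not shown to be unchanged.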

Other observations

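The tests of strain DNA near Park7, of sequencing depth and of WT OVA replicate 6 and the removal of the length and GC trend, were chosen after the results had been seen. Between DJ-1 KO OVA and WT OVA single members of further lists passed, while the lists did not, with camera adjusted p = 0.7 for alveolar macrophages, 0.44 for plasma cells and immunoglobulins, 0.23 for glycolysis and 0.48 for chemokines. Of alveolar macrophage genes 3 of 12 fell and 1 rose: Marco, a scavenger receptor, fell from 24.8 ± 4.03 to 3.64 ± 2.12 FPKM (SD, n = 3), Cidec from 32 ± 6.9 to 9.7 ± 3.16, and Mrc1, the mannose receptor, rose from 23.7 ± 2.56 to 91 ± 43.6. Of 17 measured immunoglobulin and plasma cell genes 2 rose and 2 fell: Ighg1 and Irf4 rose (14.1-fold and 4.29-fold), while the light chain Iglc2 (219 ± 72.9 to 58.7 ± 36.6 FPKM) and Sdc1 (74.4 ± 17.3 to 38.2 ± 8.57) fell. Of 16 glycolysis genes 2 rose and 1 fell: Pfkp and Hk2 rose 2.47-fold and 2.61-fold, and the lactate exporter Slc16a3 fell from 80.8 ± 11 to 30.2 ± 15.8 FPKM. Of these genes only Marco, Cidec, Mrc1, Ighg1 and Irf4 passed whichever library was left out; without DJ1_KO_OVA_267 the adjusted p was 0.078 for Iglc2, 0.13 for Sdc1, 0.08 for Pfkp, 0.15 for Hk2 and 0.081 for Slc16a3. Among chemokines 5 of 29 measured members rose and 0 fell, and Cxcl12 rose from 6.77 ± 0.416 to 16.4 ± 1.22 FPKM. After rescaling to equal FPKM sums 4 alveolar macrophage genes were higher and 3 lower, and 6 plasma cell and immunoglobulin genes were higher and 1 lower. For glycolysis 9 were then higher and 1 lower, and for chemokines 9 higher and 0 lower. The lowest camera adjusted p over the alternative settings was 0.0089 for glycolysis and 0.0049 for chemokines.

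Called genes were more frequent on the part of chromosome 4 that holds Park7, but not in the 10 Mb bin where the gene lies. Within 20 Mb of Park7 77 of 366 other genes were called between DJ-1 KO OVA and WT OVA (21%), against 14% elsewhere, a ratio of 1.5 (two-sided Fisher exact p = 0.00034). Within this window the excess lay from 130 to 140 Mb (24.9%) and from 140 to 150 Mb (22.9%). From 150 to 160 Mb, where Park7 lies, 14 of 99 genes were called (14.1%, a ratio of 1.01). In the list of genes near Park7 fixed beforehand, 3 of 16 measured members were called (camera adjusted p = 0.91). The highest share of any 10 Mb bin of the chromosome lay far from Park7, from 0 to 10 Mb (7 of 25 genes, 28%). By whole chromosome, 17.7% of genes were called on chromosome 16 and 17.4% on chromosome 4. No other window of this size was compared, and the exact test treats neighbouring genes as independent. DNA from another strain flanking the knocked-out gene stays undecided: 10 of the 100 genes with the smallest p lay within the 20 Mb (a ratio of 5.33, exact p = 3.8e-05) and DJ-1 KO OVA against WT PBS, with the same knockout libraries, gave a ratio of 1.86 (exact p = 1e-05), but the bin of Park7, a condition added after its value had been seen, had no excess. Reads divided between near-identical zinc finger genes stay open as a part, since without Zfp and Gm-numbered genes the ratio of shares was 1.45 (exact p = 0.0021), under the 1.5 set beforehand to argue against them, while the odds ratio was 1.56, above the 1.2 set to argue for them; a biological effect of DJ-1 on this region was not tested.

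Many genes differed between DJ-1 KO OVA and WT OVA. The tables argue against depth as the cause. The 3 knockout libraries were deeper than the 3 WT OVA libraries, but with every library thinned at random to 20812192 reads 2404 genes passed and 93.1% of the calls remained. After quantile normalization 2394 genes passed, within the bounds set beforehand to argue against the authors' scaling. That setting moved the median of all genes by only 0.028 on the log2 scale, so it tests the scaling weakly. Rescaling to equal FPKM sums moved the median by 0.524 and gave 5176 genes, 1668 of them among the 2510. Many genes passed under each scaling, but the share that was higher went from 41.9% to 87.9%, so their direction depends on the scaling. Bias by gene length and GC content may account for part and stays undecided: 63.5% of the calls remained after the trend was removed, below the 67% set beforehand to argue against it, while the count did not fall to the level set to argue for it. More nuclear RNA in the knockout libraries is also undecided, since the 7 measured nuclear-retained RNAs had a median difference of 0.047, under the 0.25 set to argue against it, but 4 were higher and 3 lower, from -0.31 to 1.07, and such a median decides nothing. A cohort or library batch cannot be told apart from the genotype, because 0 batches named in the labels hold both genotypes, and the genotype itself remains open.

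WT OVA replicate 6 lay between the PBS group and the other OVA replicates, with a mucus list mean of 2.73, against 4.43 and 4.07 in WT OVA replicates 5 and 9 and 1.61 to 2 in the WT PBS libraries. A swap that put a sample responding like WT OVA replicates 5 and 9 among the PBS libraries is argued against. In the 15 members of the alternative macrophage activation list that the mucus list does not hold, 0 PBS libraries reached the lower of those replicates. The PBS means were 3.73 to 4.41, against 5.81 and 5.42 in replicates 5 and 9. Replicate 6 was at 4.51, only 0.1 above the highest PBS library, so a swap with a weakly responding sample could not be detected. An unchallenged sample with a wrong label stays open. Over 50 genes chosen without replicate 6 and outside the mucus list, on a scale from 0 for the PBS libraries to 1 for WT OVA replicates 5 and 9, replicate 6 had a median position of 0.31 to 0.33, and PBS libraries held out of the choice had -0.01 to 0.23, so it lay above them by less than the PBS libraries span. Rnase2a, chosen here after its values were seen, lay farther above, at 2.09 FPKM in replicate 6 against at most 0.212 in the PBS libraries. Tmem150a was at 2.28 against at most 0.441, but it was called with replicate 6 in the fit, so it cannot place that library. In the challenged knockout libraries Tmem150a was at 0.113, 0.191 and 0.238 FPKM. A weaker response to challenge in the sample of replicate 6 is open too and was not tested.

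In the 10 splits of the 6 libraries of each comparison, 1 split, the real one, gave the most genes: 1 against a highest other of 0 for WT OVA against WT PBS, 2510 against 1 for DJ-1 KO OVA against WT OVA, and 1513 against 1 for DJ-1 KO OVA against WT PBS. With 10 splits no share under 0.05 can be reached. Every other split mixes the 2 groups, so a difference between the groups, whatever its cause, enters the spread. The counts of the other splits are therefore not a chance level for the real count.

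The 12 mitochondrially encoded protein genes other than mt-Nd3 had differences of -2.35 to -0.86 between DJ-1 KO OVA and WT OVA (median -1.33), against -3.94 for mt-Nd3, and mt-Tg had 0, 0 and 0.601 FPKM in the knockout libraries. Gapdh, named with Pdpn and Actb after their values had been seen, was at only 1.08 to 2.3 FPKM in the 9 libraries and Pdpn at 0 to 0.028, while Actb was at 706 to 1150. Xist was at 21 FPKM in DJ1_KO_OVA_263 and at 3.08 to 10.4 in the other 8 libraries.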
